A study of Homo sapiens with 2 samples.

How the data were processed

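Total RNA of 2 cultures of the MyLa cell line, 1 with an empty GFP vector and 1 with a miR-26a GFP vector, was labelled with Cy3 and hybridised to 1 Agilent array each, per the labels. Both arrays lay on the same slide and were scanned together, so slide and scan could not differ between the groups. The scanner values are linear intensities made with Agilent Feature Extraction 11.5.1.1, per the file headers. That software subtracted the local background and removed a spatial trend within each array before the authors deposited the processed intensities, and it applied no scaling between arrays. Other columns hold flags for spots above background, saturated or outlying, per the file headers. The authors also deposited a table of log2 values whose making is not given in the sources used here. The difference between its columns followed the scanner's log2 difference with a slope of 1.00 and an offset of 0.32 (r = 1.00 across probes), which settled its log2 scale and its direction. The 2 columns summed to 0 for every probe (largest sum 0.0000), so each probe was centred between the arrays. The column medians of that table were 0.10 for the empty vector and -0.10 for miR-26a. The constant subtracted per array is unknown.

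Each array held 62976 spots, 58717 of them for genes. Control spots and outlier spots (352 and 351) were left out, and spots of a probe were averaged, which removed 1 probe. The log2 of the processed intensity was set relative to the 75th percentile of each array, 181.6 for the empty vector and 227.2 for miR-26a, a shift of 0.32. The 7 brighter spike-in controls differed by a median of 0.02 before that scaling and the dimmest one above background by -0.26, so on a scale set by those spike-ins every log2 difference is 0.30 higher. That constant leaves list percentiles as they are and can turn the direction of smaller differences. A gene's value was the mean over its probes well above background on both arrays (26883 probes, 53.1%). Probes disagreed in direction for 1040 of the 3570 genes with several, and for 9 genes past 2-fold. A gene above background on 1 array only was given as a lower bound, the bright value against the higher of the dim probe's own signal and the lowest signal among probes well above background on that array.

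The files name probes by accession, and symbols came from a RefSeq gene table (GRCh38.p14) through unversioned accessions. Of the probes 28928 matched 1 symbol, 0 matched several and 21566 matched none. The array was designed on hg19, so no coordinates are printed, and the table served for names and gene order only. XIST and genes found only on chromosome Y (104 probes) were left out of all results.

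With 1 array per group no test was run. The scanner's error model gave an error of 0.20 in the log2 difference of a gene with 1 probe, 0.15 with 2 and 0.12 with 3, and the 627 probes well above background among 902 spotted 10 times gave the spot noise. For precision, the number of arrays is the limit. A list's median was placed among 10000 random lists of the same size, drawn within 20 bins of mean signal, as a description of these 2 arrays and not a p-value, with 2000 random lists for the alternatives. The 33 lists were written from general knowledge before the data were examined, as were the rule for named genes and the alternatives other than those named as added. That rule took the 12 genes furthest up and the 12 furthest down among genes at or above the median signal whose probes all moved one way, the 3 largest bounds in each direction among genes seen on 1 array, up to 4 members of each list furthest from 0, and 8 genes tied to miR-26a. Clone and accession names were left out, and a few list members are not reported here. CCL22 was named by that rule, and CCR4, CD69, IFIT1, IFI44, IFI44L, CXCL9, MX1, GBP2, IRF7, TCF7, PLOD2 and NOS2 are list members outside the rule, named after their values were seen.

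The steps were tested on simulated data for the miR-26a against empty vector comparison with 14129 genes and spot noise only. All 100 genes changed 3-fold and all 100 changed 4-fold passed 2-fold, as did 27 of 13895 unchanged genes (0.194%). Of 100 lists of unchanged genes 6 lay outside the central 95%. Alternatives were quantile normalization, median scaling, the authors' table, no filter on dim probes, brighter probes only, the brightest probe of each gene, a loess correction (span 0.3), and thresholds of 1.5-fold and 3-fold. Added after seeing the data were normexp background correction (offset 50) on the median intensity, removal of the local median within 10 rows and columns of the slide, removal of each chromosome's median, and scaling to the 7 brighter spike-ins. The normexp offset is added to each signal and so shrinks the log2 differences of dim probes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and R 4.3.3 with limma 3.58.1 were used.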

Results

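Gene expression was measured in MyLa, an established cell line of cutaneous T cell lymphoma, after transduction with a GFP vector. One culture carried the empty vector and the other a vector that also expressed miR-26a, a small RNA that lowers the level or the translation of messenger RNAs it pairs with. Each culture gave 1 Cy3-labelled RNA on 1 Agilent array, so 2 samples were compared and each group held 1 array. There was no replicate check for any difference below, and no p-value was computed. Each array carried 50599 gene probes, of which 28251 (55.8%) lay well above background with the empty vector and 29226 (57.8%) with miR-26a. Both arrays measured 14129 named genes well above background, and no spot was saturated. Differences are miR-26a minus empty vector on the log2 scale, each array set to its 75th percentile, with the error of the scanner's own model after ±. That error and the repeat spots cover spot noise only, not the spread between cultures, RNA extractions, hybridisations or the different probes of a gene.

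The submitters ran the comparison to find genes whose expression is lower with miR-26a. Among the genes above the median signal, LAT2, an adaptor protein of immune receptor signalling, was the furthest below its empty vector level, at a log2 difference of -4.64 ± 0.21, or 24.97-fold lower. CCL17, a chemokine that attracts T cells carrying CCR4, was 8.97-fold lower (-3.16 ± 0.20) and was bright on both arrays. CCL22, the other ligand of CCR4, was well above background only with the empty vector and was at least 19.5-fold lower with miR-26a, while CCR4 itself differed by -0.18 ± 0.21. IGFL2, a member of the insulin growth factor-like family, was 8.96-fold lower (-3.16 ± 0.20). GPAT2, a glycerol-3-phosphate acyltransferase, was 6.99-fold lower (-2.80 ± 0.13, 3 probes), and HOPX, a homeodomain protein of T cells among other cells, was 6.70-fold lower (-2.74 ± 0.15, 2 probes). The GPAT2 probes disagreed in size, at -4.62, -1.91 (the brightest) and -1.88, as did the HOPX probes, at -4.40 and -1.09 (the brighter). The error after ± leaves that disagreement out. The HOPX probes had like empty vector signals (1.80 and 1.89), so the brighter was so mainly through its smaller fall. Normexp background correction gave -3.76 for LAT2, -2.16 for GPAT2, -2.03 for HOPX and -2.07 for ZDHHC14. The palmitoyltransferase gene ZDHHC14 was 6.46-fold lower (-2.69), the noncoding RNAs LINC00926 and NRAD1 were 6.11-fold and 5.58-fold lower (-2.61 and -2.48), and CYSRT1 was 4.48-fold lower (-2.16), or -1.05 without the filter on dim probes. ARHGEF3 was 4.06-fold lower (-2.02), the serine dehydratase-like gene SDSL 3.79-fold lower (-1.92), and the imprinted gene PHLDA2 3.65-fold lower (-1.87).

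CPB1, a carboxypeptidase known from the pancreas, was 69.7-fold higher with miR-26a (6.12 ± 0.21). TRIM43 was 14.9-fold higher (3.89, or 6.53 without the filter on dim probes), the atypical cadherin FAT1 13.9-fold (3.80) and the germ cell gene TEX19 13.5-fold (3.76). P2RY8, a G protein-coupled receptor of lymphocytes, was 14.1-fold higher (3.82), and IL3RA, the alpha chain of the interleukin-3 receptor, was 11.7-fold higher (3.55). Both lie in the pseudoautosomal region at the start of chromosome X, where all 15 measured genes were higher with miR-26a, with a median difference of 1.35. ANKRD55 was 8.01-fold higher, LINC00892 7.14-fold (2.84, 2 probes) and ISG15, an interferon-induced ubiquitin-like modifier, 6.56-fold (2.71). The receptor tyrosine phosphatase PTPRM was 6.41-fold higher (2.68), PLXDC2 5.91-fold (2.56) and FLRT3 5.46-fold (2.45). Normexp background correction gave 5.45 for CPB1 and 2.09 for PTPRM. Among genes well above background only with miR-26a, the lipid transporter ABCA12 was at least 104.5-fold higher, the synaptic gene UNC13C at least 52.3-fold and the protease TMPRSS11B at least 44.8-fold. Among those seen only with the empty vector, after CCL22, SNORD115-3 was at least 18.7-fold lower and the zinc finger gene ZNF813 at least 16.3-fold lower. SNORD115-3 belongs to a family of closely similar copies, and whether its probe separates them was not tested.

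**Figure D1:**
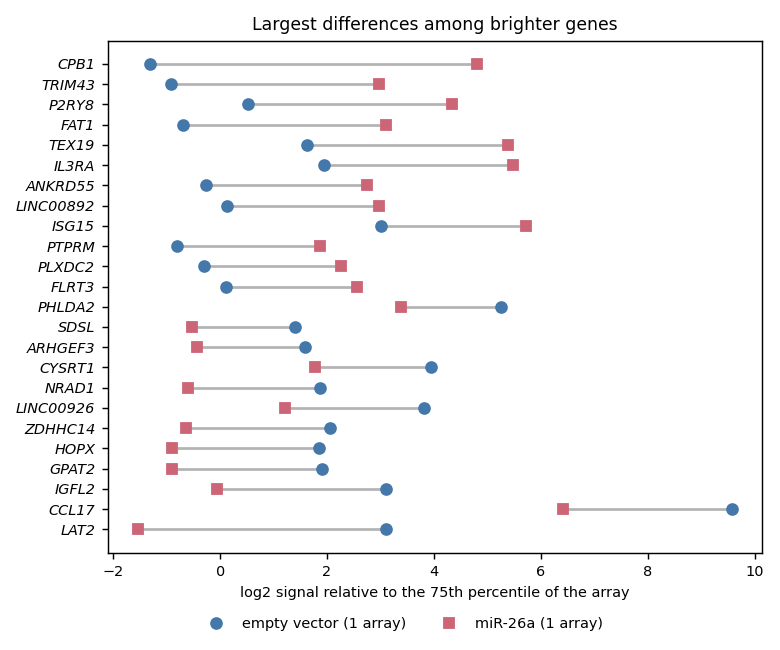
Normalised log2 signal (relative to the 75th percentile of each array) of the 12 genes furthest above and the 12 furthest below their empty vector level among genes at or above the median signal, with a circle for the empty vector array and a square for the miR-26a array, 1 array each. CPB1 stood 6.12 higher with miR-26a, and CCL17 differed by -3.16 from the highest empty vector signal of the genes shown.

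In all, 518 genes (3.67%) were at least 2-fold higher with miR-26a and 444 (3.14%) at least 2-fold lower, and 89 and 49 passed 4-fold. The other 93.2% of genes lay within 2-fold, the median difference was -0.05 and the quartiles were -0.33 and 0.26. A further 787 genes were well above background only with miR-26a, 274 of them by a bound of at least 2-fold, and 438 only with the empty vector, 202 of them by such a bound. Spots of the same probe differed by a median SD of 0.06 in the log2 difference for brighter probes and 0.16 for dimmer ones, so a 2-fold difference exceeded the typical spot noise. The 95th percentile of that SD was 0.12 for brighter and 0.73 for dimmer probes, so for the noisiest dim probes a 2-fold difference was close to spot noise. With normexp background correction the counts were 244 higher and 137 lower, so that 64.0% of the genes past 2-fold were higher against 53.8% above. That correction adds an offset of 50 to each signal, above the median processed signals of 23.5 (empty vector) and 28.6 (miR-26a). The offset by itself pulls the log2 differences of dim genes toward 0. Without the filter on dim probes they were 1148 and 1234, and with brighter probes only they were 193 and 136. Scaled to the brighter spike-in controls in place of the 75th percentile, every difference was 0.30 higher, the median over all genes was 0.25, and 1040 genes were at least 2-fold higher and 211 lower (83.1% higher). Directions of smaller differences are therefore relative to the 75th percentile of each array.

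Genes reported elsewhere as miR-26a targets were not lower as a group. The list was written from general knowledge and not chosen from these samples. Of its 40 genes 34 were measured, with 19 lower, 15 higher, and a median difference of -0.04 (percentile 52.4 among random lists of equal size and signal, whose central 95% ran from -0.21 to 0.14). IL6, an inflammatory cytokine, was 2.15-fold lower (-1.10 ± 0.20) and CDK6, a kinase that drives entry into the cell cycle, was 2.06-fold lower (-1.04 ± 0.20), the 2 members past 2-fold. On the spike-in scale neither passed 2-fold, 11 of the 34 were lower and the median was 0.26, at the same percentile. HGF differed by -0.82 (-1.62 without the filter on dim probes) and the kinase MAP3K2 by 0.74. EZH2, the catalytic subunit of the Polycomb repressive complex, was 0.47 ± 0.20 higher, and the cyclins differed by -0.04 for CCNE1, -0.04 for CCNE2 and 0.21 for CCND2. Of the remaining 6 genes, PLOD2 was seen only with miR-26a and NOS2 only with the empty vector. The miR-26 genes lie in introns of CTDSPL, CTDSP2 and CTDSP1, whose own messages differed by 0.24, -0.40 and 0.41 (median 0.24, percentile 82.4). The brightest probe of each gave -0.67 for CTDSP2 and 0.67 for CTDSP1. No probe was named for miR-26a itself, so the arrays gave no check of its level.

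Genes of cell division were higher with miR-26a. Of 30 mitosis genes 29 were higher, by a median of 0.60, above all 10000 random lists. ANLN, which builds the cleavage furrow, was 1.13 higher, CDC20, an activator of the anaphase-promoting complex, 1.12, the centromeric histone CENPA 1.11 and the kinesin KIF20A 1.06. Of 29 measured genes of DNA replication and the G1/S transition 25 were higher, by a median of 0.50, again above all random lists. They included the ribonucleotide reductase subunit RRM2 at 1.44, CDC45 at 1.42, MCM10 at 1.34 and cyclin A2 (CCNA2) at 1.20. MCM10 was 0.66 higher with normexp background correction. The replication-dependent histone genes did not stand apart as a list, with a median of 0.12 over 12 genes (percentile 87.2) and the member furthest from 0, H3C4, at 0.59. With the brightest probe of each gene that median was 0.25 (percentile 97.65), just outside the random range.

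Hypoxia and glycolysis genes were higher by a median of 0.71, with 18 of 20 higher, 6 of them at least 2-fold, above all random lists. BNIP3, a mitochondrial protein of hypoxic cells, was 1.55 higher, the glucose transporter SLC2A3 1.48, the glycolytic kinase PGK1 1.40 and ANKRD37 1.27. The oxidative phosphorylation genes had a median of 0.01 (percentile 72.2), with cytochrome c (CYCS) at -0.59, or -0.37 with normexp background correction. MYC and ribosome biogenesis genes had a median of 0.14 (percentile 95.8), with lactate dehydrogenase LDHA at 1.01 and RRP12 at -0.79.

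Targets of p53 were low relative to other genes of like signal, with 21 of 23 below 0 and a median of -0.30 (percentile 0.57). On the spike-in scale the median was -0.0022 and 12 of 23 were lower. TP53INP1 differed by -1.45, the DNA repair gene XPC by -1.04, TP53I3 by -0.67 and CDKN1A, an inhibitor of cyclin-dependent kinases, by -0.67. TP53INP1 differed by -0.84 with normexp background correction. Ribosomal protein genes lay below 0 in 21 of 22 cases, with a median of -0.25 (percentile 0.91) and RPS3 at -0.51, but on the spike-in scale the direction turned, with a median of 0.045 and 17 of 22 higher. They were the brightest list, and with quantile normalization or a loess correction of signal their medians were -0.0052 and -0.069, inside the range of random lists, as was the median with brighter probes only.

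Interferon response genes were high relative to other genes of like signal. Of 20 measured members 12 were higher and 8 lower (17 and 3 on the spike-in scale), with a median of 0.35 (percentile 99.97), or 0.15 with normexp background correction (percentile 98.4). The chemokine CXCL10 was 16.5-fold higher (4.05), ISG15 was 2.71 higher, IFIT3 2.32 and OASL 2.07. GBP2, a guanylate-binding protein, differed by -1.66 and IRF7, a regulator of type I interferon genes, by -0.9982. IFIT1, IFI44, IFI44L and CXCL9 were seen only with miR-26a and MX1 only with the empty vector, at least 3.10-fold lower with miR-26a. The NF-kB target genes were higher in 13 of 18 cases (17 on the spike-in scale) by a median of 0.28 (percentile 99.5), with CXCL8 at 1.66, the lymphotoxin genes LTB and LTA at 1.51 each and CCL3 at 1.25. With that correction, CXCL10 was 2.92 higher, IFIT3 1.29 and CXCL8 0.48.

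Several T cell surface and regulatory genes were higher with miR-26a. CTLA4, an inhibitory receptor, was 20.4-fold higher (4.35), the Ikaros family factor IKZF2 was 2.08 higher, CD40LG, the ligand by which T cells activate B cells, 1.98 and TOX 1.29. CD69, an early activation antigen, was seen only with miR-26a, at least 34.9-fold higher. The T cell activation and checkpoint list had 11 of 18 genes higher (16 on the spike-in scale) and a median of 0.28 (percentile 99.3). That median fell inside the random range without the filter on dim probes or with brighter probes only (both 0.12). It also fell inside after each chromosome's median was removed (0.21), a step that leaves differences of shorter chromosome stretches in place. In the T cell identity list the costimulatory receptor CD28 was 2.54 higher, CD3G of the T cell receptor complex 2.25, CD2 1.84 and BCL11B 1.24, while TCF7 differed by -1.03. That list had 12 of 18 genes higher (15 on the spike-in scale) and a median of 0.20 (percentile 97.4), just inside the random range. Its percentile ran from 94.9 (no filter on dim probes) to 99.5 (brightest probe of each gene) across the alternatives. It was 97.85 with median scaling, which adds only a constant, so passing the edge there reflects the redrawn random lists. With normexp background correction, CTLA4 was 3.22 higher, IKZF2 0.81, CD28 1.58 and BCL11B 0.74. The brightest probes of IKZF2 and CD28 were 3.75 and 3.37 higher, but the other probe measured on both arrays gave 0.41 for IKZF2 and 1.72 for CD28. The 2 IKZF2 probes had like empty vector signals (-3.55 and -3.51), so the brightest was so only through its higher miR-26a signal. Cytotoxic genes were mostly dim, with 4 of 14 measured, a median of 0.20 (percentile 87.9) and GZMH at 0.76. With normexp background correction that median was -0.0063 and GZMH differed by -0.060. The list of genes linked to cutaneous T cell lymphoma had a median of 0.18 (percentile 92.0), with STAT4 at 1.77 and TWIST1 at 0.76, or 0.67 and 0.33 with normexp background correction.

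Cytokines and their receptors differed in both directions. CSF2, which encodes GM-CSF, differed by -2.35 and IL22 by -1.90, while the type 2 cytokines IL5 and IL13 were 1.75 and 1.47 higher. With normexp background correction, CSF2 differed by -1.52, IL22 by -0.66 and STAT4 by 0.67. The 11 measured cytokines had a median of 0.12 (percentile 84.0), and 9 others were seen on neither array or on 1. The cytokine median was -0.16 without the filter on dim probes and -0.02 with the local slide median removed, both inside the random range. It was 0.46 with brighter probes only and 0.18 with normexp background correction, both outside. Among cytokine receptors and JAK-STAT genes, the feedback inhibitor SOCS3 differed by -1.96 and the interleukin-7 receptor IL7R by -1.85, while STAT4 and the common gamma chain IL2RG were 1.77 and 1.11 higher (list median -0.10, percentile 26.1). The chemokine receptor and homing list, which holds CCL17, had a median of -0.04 (percentile 51.02), and S1PR1 and SELPLG were 0.64 and 0.68 higher.

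The other lists fell inside the range of their random lists. The medians were -0.01 for apoptosis regulators of the BCL2 and IAP families (BMF -0.99, BCL2 0.71), 0.05 for polycomb and chromatin modifiers (DNMT3B 0.76), 0.14 for ATF4 and unfolded protein response genes (CHAC1 -1.34, DDIT4 1.06) and 0.13 for heat shock genes (HSPA1B -0.79). They were 0.10 for cholesterol synthesis genes (SC5D -0.78), -0.06 for immediate early genes (SPRY1 1.47, DUSP6 -1.22), -0.23 for TGF-beta and BMP response genes (ID2 0.88) and 0.18 for microRNA processing genes (AGO4 0.52). Without the filter on dim probes the immediate early median turned to 0.17, outside the random range. With normexp background correction BMF differed by -0.59, BCL2 by 0.36, DNMT3B by 0.32, SC5D by -0.47 and AGO4 by 0.23. Markers of other cell types were inside as well. Their medians were -0.44 for B cells (5 of 10 measured), -0.12 for myeloid cells (5 of 12), -0.19 for fibroblasts (5 of 10), -0.01 for keratinocytes and epithelium (5 of 10), 0.05 for endothelium (3 of 8) and -0.12 for erythroid cells (5 of 8). The B cell median turned to 0.55 with brighter probes only and was -0.44 with chromosome medians removed, both outside the random range. Members past 2-fold were BLK at 1.03 and COL1A1 at -1.69, the latter at -0.9966 with normexp.

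**Figure D2:**
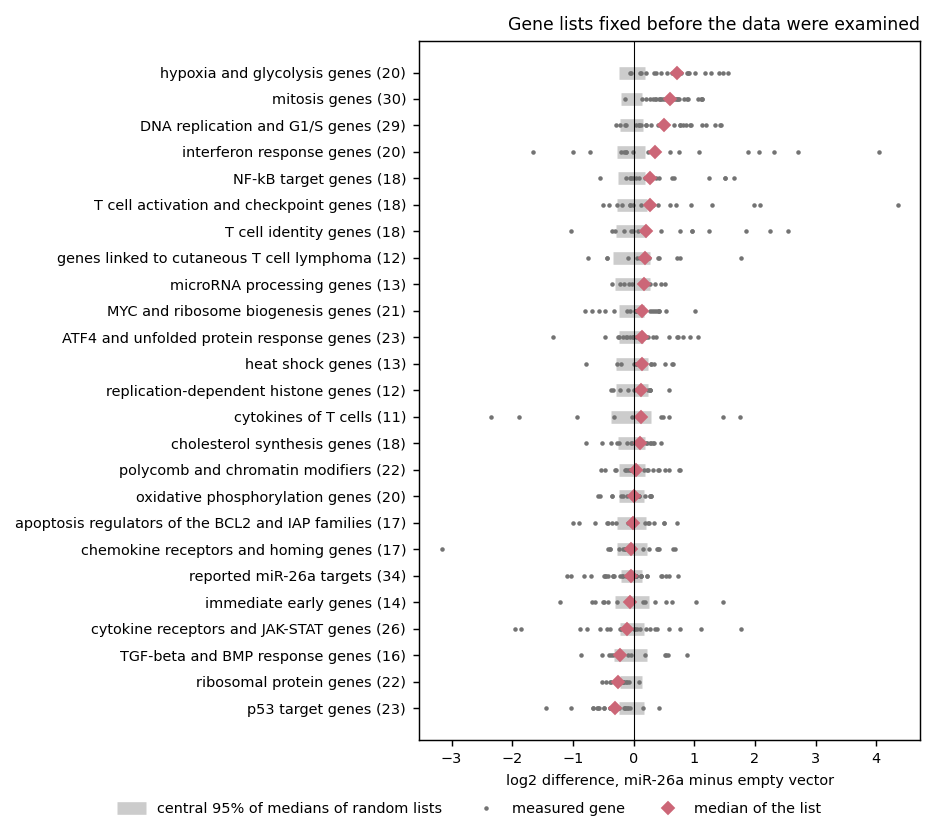
Log2 difference (miR-26a minus empty vector, 1 array each) of the measured genes of each list with at least 11 of them (dots, number in brackets), the list median (diamond) and the central 95% of medians of 10000 random lists matched on signal (grey bar). The hypoxia and glycolysis (0.71), mitosis (0.60) and DNA replication (0.50) medians lay to the right of their bars, and the ribosomal protein (-0.25) and p53 target (-0.30) medians to the left.

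Of the 33 lists, 8 had a median outside the central 95% of random lists, 6 above and 2 below. Among lists of genes drawn singly, 5% would lie outside by construction. Lists whose members vary together can lie outside more often, so the 8 are not an excess to be read against that 5%. Whole chromosomes also stood apart. Genes of chromosomes 11, 15, 17 and 3 had medians of -0.26, -0.22, -0.21 and -0.19, and genes of chromosomes 4 and X of 0.14 and 0.11, with 19 of 23 chromosome medians outside the central 95% of 1000 random lists. That range is narrow for so many genes, and chromosome 16 lay outside at a median of 0.004. On the spike-in scale every median is 0.30 higher and lies above 0, so only the order of the chromosomes holds on both scales.

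**Figure D3:**
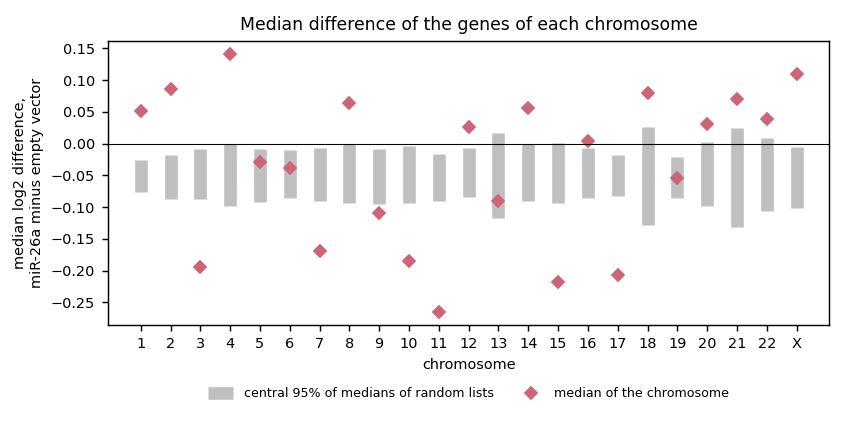
Median log2 difference (miR-26a minus empty vector, 1 array each) of the measured genes of each chromosome (diamond) and the central 95% of medians of 1000 random lists of equal size and signal (grey bar). Chromosome 11 lay lowest at -0.26 and chromosome 4 highest at 0.14.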

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

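Probes without a gene symbol were left out of every gene count, yet many differed between the arrays. Of the 8038 measured, 277 were at least 2-fold higher with miR-26a and 356 at least 2-fold lower, a share of 7.88% against 6.79% of named probes. None of the 40 control probes above background on both arrays passed 2-fold. What these probes measure was not resolved here, and no explanation was tested.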

How the results depend on the processing

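The 1 array per group limits every value. The counts of genes at least 2-fold higher with miR-26a and genes at least 2-fold lower with miR-26a (518 and 444) were 244 and 137 with normexp, 1148 and 1234 with no filter on dim probes, and 193 and 136 with brighter probes only, where fewer genes enter. They were 1446 and 1591 at 1.5-fold, and 168 and 111 at 3-fold. With spike-in scaling they were 1040 and 211, since it adds 0.30 to every difference; list percentiles stay as they are, and of the 8 lists outside the random range ribosomal protein genes turned direction (0.0452). Of the 518 and 444 genes, 230 and 137 also passed with normexp. It was run on the median signal in place of the processed one and with an offset of 50, so these choices changed together. The reported targets' median stayed inside its random range in all 11 alternatives, from -0.07 (local slide median removed) to 0.26 (spike-in scaling). In the other 10, across lists 298 settings kept the side of the random range, 19 moved a list outside and 6 moved one inside; no list outside turned direction. The T cell identity median moved outside with normexp (0.18), quantile (0.22), median scaling (0.22), the authors' table (0.20), brighter probes (0.28), the brightest probe (0.28) and chromosome medians removed (0.24). T cell activation genes moved inside with no filter (0.12), brighter probes (0.12) and chromosome medians removed (0.21). Ribosomal protein genes moved inside with quantile (-0.0052), loess (-0.069) and brighter probes (-0.25, the same genes against another random pool). Also moved outside were cytokines with normexp (0.18) and brighter probes (0.46), ATF4 genes with normexp (0.19) and the slide correction (0.18), MYC genes with loess (0.22) and the slide correction (0.17), histone (0.25) and polycomb genes (0.20) with the brightest probe, cytotoxic (0.24) and immediate early genes (0.17) with no filter, and B cell markers with brighter probes (0.55) and chromosome medians removed (-0.44). Median scaling adds a constant and leaves percentiles as they are, so the T cell identity move there (97.4 to 97.85) reflects the redrawn random lists. The moves with the authors' table (97.70), quantile (97.55) and chromosome medians removed (97.55) were no larger than that. The causes of the other changes were not tested. For single named genes, spike-in scaling aside, 1238 settings kept the value within its scanner error and 103 did not. Many of the 1238 could hardly have moved. Median scaling adds a small constant, the authors' table nearly so, and the brightest probe is the same probe where 1 was measured. Most of the 103 came with normexp. Normexp on the mean signal and all tests of miR-26a seed sites were not run, for want of that column and of 3' UTR sequence. No paired analysis was possible because each group holds 1 array.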

Other observations

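Metallothioneins, small proteins that bind zinc and copper, were lower with miR-26a in 9 of 10 measured cases, by a median of -1.29, below all 10000 random lists. MT1X differed by -1.66, MT2A by -1.37 and MT1E by -0.79, while MT1G was 0.23 higher and MT3, at -0.29, lay within the 0.30 between this scale and that of the spike-ins. Killer cell immunoglobulin-like receptor genes were higher in 10 of 10 cases by a median of 0.76, with KIR2DL2 at 0.84, KIR3DL1 at 0.94 and KIR3DL2 at 0.39. Members of both families are close in sequence, and whether their probes separate them was not tested. Both groups were picked after their values were seen.

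Genes of the pseudoautosomal region at the start of chromosome X were higher as a block, 15 of 15 measured, 13 of them at least 2-fold, by a median of 1.35. Besides P2RY8 and IL3RA they included the adhesion molecule CD99 at 1.98, DHRSX at 1.68, ZBED1 at 1.54 and CRLF2, a cytokine receptor chain, at 1.28. This block was also picked after its values were seen.

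Of the tests below, the slide surface, tandem family and copy number tests were set before their results were seen, and the others after. Genes next to each other on a chromosome tended weakly to differ in the same direction, with a Spearman rho of 0.16 across 14101 pairs of genes (shuffled orders -0.02 to 0.02), which are not independent replicates. Tandem families are argued against as the whole cause, since neighbours with different first 3 letters kept a rho of 0.1535. The gene-rich chromosomes 22 and 17 lay on opposite sides of random lists, 0.2454 apart. That cannot decide on base composition, since this comparison was set after the results were seen and base composition itself was not measured. Segments present in different copy number in the 2 cultures are a candidate explanation, with a mean rho of 0.0741 over pairs 10 to 50 genes apart (shuffled orders -0.0027 to 0.0023). Chromosome medians were not removed for that value, so shifts of whole chromosomes enter it too. It cannot tell such segments from another cause shared along a chromosome. No DNA was measured. Whether position on a chromosome accounts for genes named together above, such as CCL17 and CCL22 or CTLA4 and CD28, or for the metallothioneins, was not tested.

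The higher mitosis, replication and glycolysis genes were set against technical causes. After a loess correction for a trend with signal, the lowest of the 3 medians was 0.5386. That test was set after the results were seen and decides little. The lists already stood above all random lists of like signal, which would share such a trend. An uneven slide is argued against, since the lowest median was 0.5072 after the local slide median was removed. Both medians lay above the random range. The growth state of the culture at harvest cannot be told apart from the effect of miR-26a, with 1 array per vector. A faster-growing or denser miR-26a culture may therefore give the same pattern as miR-26a itself.

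The reported miR-26a targets did not shift as a list, although 85% of the list was well above background on both arrays. The median signal of those measured members lay at percentile 64.7 of the genes measured on both arrays, which leaves out the 6 others. The comparison for dim probes was set after the results were seen, so these values describe the measured members and are not a test. Whether miR-26a was active in the sampled culture cannot be told, since 0 probes were named for a miR-26 gene. In simulated spot noise, a list of 34 genes lowered by 0.4 lay below all random lists. The simulation leaves out differences between cultures, and effects on translation would not show in RNA.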
